A study of Homo sapiens with 12 samples.

How the data were processed

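The data were 12 single-cell RNA libraries of human bone marrow from femoral heads, made with the 10x Genomics Single Cell 3' kit. Per the labels' protocols, tissue was digested with enzymes and depleted of red blood cells, then 67% of the remaining cells were depleted of CD45-positive blood cells and 33% were enriched for CD34-positive progenitors. Cells of the 3 fractions were pooled before loading, per the labels' protocols, so each library mixes unenriched, stroma-enriched and progenitor-enriched cells in a ratio that the sources used here do not give. The labels put all libraries in 1 group, and libraries are named here by replicate number from 1 to 12.

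For each library the authors deposited a matrix of raw UMI counts per gene and cell barcode, with a gene file that pairs Ensembl identifiers and symbols. The deposited counts came from Cell Ranger 6.1.2, per the file headers, and the genome build GRCh38 and Seurat version 4 are named in the submitters' processing notes. The matrices listed 33538 genes and held only barcodes of at least 500 UMIs, as tested on the files. Reads of this kit keep their strand, and Cell Ranger counts those in the sense direction of a gene. Values were whole numbers, and no normalised values or cell annotation were used. Symbols are given as in the files, where CYR61, CTGF and NOV stand for CCN1, CCN2 and CCN3.

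Cells were kept with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs. Doublets were scored per library against simulated doublets, 2 for each cell with 30 neighbours, and the highest-scoring 0.8% per 1000 barcodes was removed. The kept cells were clustered on 2000 variable genes of the counts scaled to the cell's total and log-transformed, with 30 principal components, a correction between libraries that follows the Harmony method (50 centres, penalty 2, 10 rounds), a shared-neighbour graph of 20 neighbours and Leiden clustering (resolution 1.5). Stromal and endothelial clusters were clustered again at resolution 1.5, and progenitor clusters at resolution 1. Genes of the 18 lists below were left out of the clustering.

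Clusters were named from 26 marker sets. A cluster stayed unnamed where no marker set stood out, where its leading genes belonged to another class or to a pair of classes, or where fewer than 3 of its markers were detected. It also stayed unnamed where its median UMI count was under 0.333 of that of its libraries, if it was closest to a stromal, endothelial, HSC or MPP-like or GMP-like class or had none of its own markers among its 10 leading genes. Other low-UMI clusters, such as the neutrophil-lineage-like ones, kept their name. For stromal and progenitor clusters, the last threshold was set after the clusters were seen and is tested as an added alternative. Names are rebuilt from markers, hence the ending "-like", and differ in basis from any annotation by the authors.

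For each comparison between classes, raw UMI counts were summed per library and class. Libraries with at least 20 cells of both classes entered. The sums were tested with edgeR's quasi-likelihood F test (TMM normalisation, filterByExpr), with the library as a block, and adjusted by Benjamini and Hochberg at 0.05 over genes that were used neither to cluster nor to name the cells. Both classes of a pair came from the same library, so the replicate number pairs them by construction, and the paired fit is the main one. Cells were not treated as replicates, and every p-value of a single gene measures the spread between these libraries. The p-values of the gene lists below set a list's genes against other genes under a given correlation. They do not measure how well a list repeats between libraries. The classes were formed by clustering the same cells on their expression. Genes that vary with the clustering genes can differ for that reason alone, and the p-values do not account for it. Log2 fold changes are those of the first class named over the second, with the standard error of the fit. Levels are the summed counts of a gene scaled to the total of the library and class (CPM, per 1e6 UMIs), as mean ± SD over libraries.

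The 18 gene lists held 307 genes. Each list was tested with camera on log2 CPM (prior count 2, preset correlation between genes of 0.01, library block) against all other genes kept, and again with the correlation estimated from the residuals. Members higher, lower and not passing were counted with the adjustment over all tested genes and again adjusted over the list alone. The named genes followed a rule. In each of 5 lists per comparison it took up to 2 genes higher and 2 lower with the largest log2 fold change, among members with an adjusted p under 0.05, the same direction in at least 0.8 of the library pairs and at least 10 CPM in the higher class. Among genes in no list it took the 3 higher and 3 lower by the same criteria, leaving out mitochondrial, ribosomal protein, immune receptor, LINC and Y-linked symbols, XIST and those with a dot. Other symbols of noncoding genes were not left out, so that the antisense RNA gene CHL1-AS1 was taken. A few genes that the rule took are left out of the text. CXCL12, KITLG, ANGPT1, IL7, CSF1 and VCAM1 were given for every pair of stromal or endothelial classes in which they were tested. The comparisons, tests, lists, marker sets, the rule and most alternatives were fixed before the data were examined. The marker sets and lists share no gene.

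Shares of cells per class are the mean ± SD over libraries, with an exact Clopper-Pearson interval of 95% for a single library. Intervals and floors cover counting error only. The floor for a count of 0 is 3 UMIs. Relations across libraries were tested with Pearson's r and Spearman's rho and 100000 permutations, two-sided.

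The alternatives were DESeq2 size factors, the DESeq2 Wald test, every gene with at least 1 count, no replicate block, a minimum of 50 cells, each library left out in turn, no library correction, no doublet removal, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), clustering with the list genes, an estimated correlation between genes, and cell means for the immediate-early relation. Alternatives on low-UMI clusters, on unresolved endothelial clusters, on single clusters with PTGS2 and LIF, heat shock genes or replication genes among their leading genes and on the background of the list test were added after seeing the data.

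The tests were run on simulated data made from the means and spread of each comparison, with 200 changed genes (100 by 2-fold and 100 by 4-fold) and 1 raised list of 15 genes. Of the genes changed 2-fold, 84% to 95% were recovered, and of those changed 4-fold, 98% to 100%. Between 4 and 12 of the unchanged genes were called, the raised list was called in all 6 comparisons, and of 18 unchanged lists 0 were called in 5 comparisons and 2 in HSC or MPP-like against GMP-like cells. Simulated genes were drawn independently, while correlations estimated in the real lists reached 0.781. The simulation therefore does not give the rate of false list calls among correlated genes. It also changed a far smaller share of genes than were called in the real data. The clustering was tested on 6000 simulated cells of 6 types in 4 libraries. With the number removed set to the true number, it found 98.3% of 414 doublets between types. In the real libraries, 50.8% to 70.7% of simulated doublets, pairs of like cells included, scored above the cut, so doublets may remain. The adjusted Rand index with the true types was 0.356 without and 1 with the library correction. The simulated types had equal numbers in each library, and the test used a lower resolution and fewer variable genes than the real clustering.

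Depth ran from 85467543 to 192918481 UMIs per library. No chromosome positions are given, since the files list none. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.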

Results

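The data were gene counts of single cells from human femoral head bone marrow, in 12 libraries of 1 group. The matrices held 4917 to 12425 barcodes per library (107642 in all) and 85467543 to 192918481 UMIs per library (1579298897 in all). The median barcode of a library had 5968 to 11788 UMIs. Of the barcodes, 99761 passed the cell filters, 7471 were removed as probable doublets, and 92290 cells were kept (4380 to 10645 per library). Clustering gave 64 final clusters. Of these, 12 clusters with 11460 cells stayed unnamed, and 4922 of their cells lay in 6 clusters of low UMI counts, 5.30% ± 3.66 of kept cells (SD, n = 12; 2.30% to 15.5%).

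The kept cells covered marrow stroma, vessels, stem and progenitor cells and mature blood cells. Per library, 12.4% ± 7.47 of kept cells (SD, n = 12) were reticular-like mesenchymal cells, named from markers such as LEPR and ADIPOQ, and 6.78% ± 5.66 were osteolineage-like cells, named from bone-forming markers such as BGLAP and IBSP. Smooth muscle or pericyte-like cells, called mural cells here, made up 4.73% ± 3.08, all endothelial-like cells 5.79% ± 5.06, and fibroblast-like cells 1.87% ± 2.30. HSC or MPP-like cells, the stem and multipotent progenitor class, made up 4.52% ± 3.81 and granulocyte-monocyte progenitor-like (GMP-like) cells 2.499% ± 1.52. The mature classes were led by plasma cell-like cells (17.6% ± 8.19) and neutrophil-lineage-like cells (13.4% ± 8.63), the latter with a median of only 1339 UMIs per cell. Shares varied widely between libraries. The reticular-like share ran from 2.39% in replicate 6 (177 cells; Clopper-Pearson 95% interval 2.05% to 2.76%) to 26.4% in replicate 12 (2159 cells; 25.5% to 27.4%). Because 3 depleted or enriched fractions were pooled, these shares are set partly by the enrichment and do not give the makeup of the tissue.

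**Figure D1:**
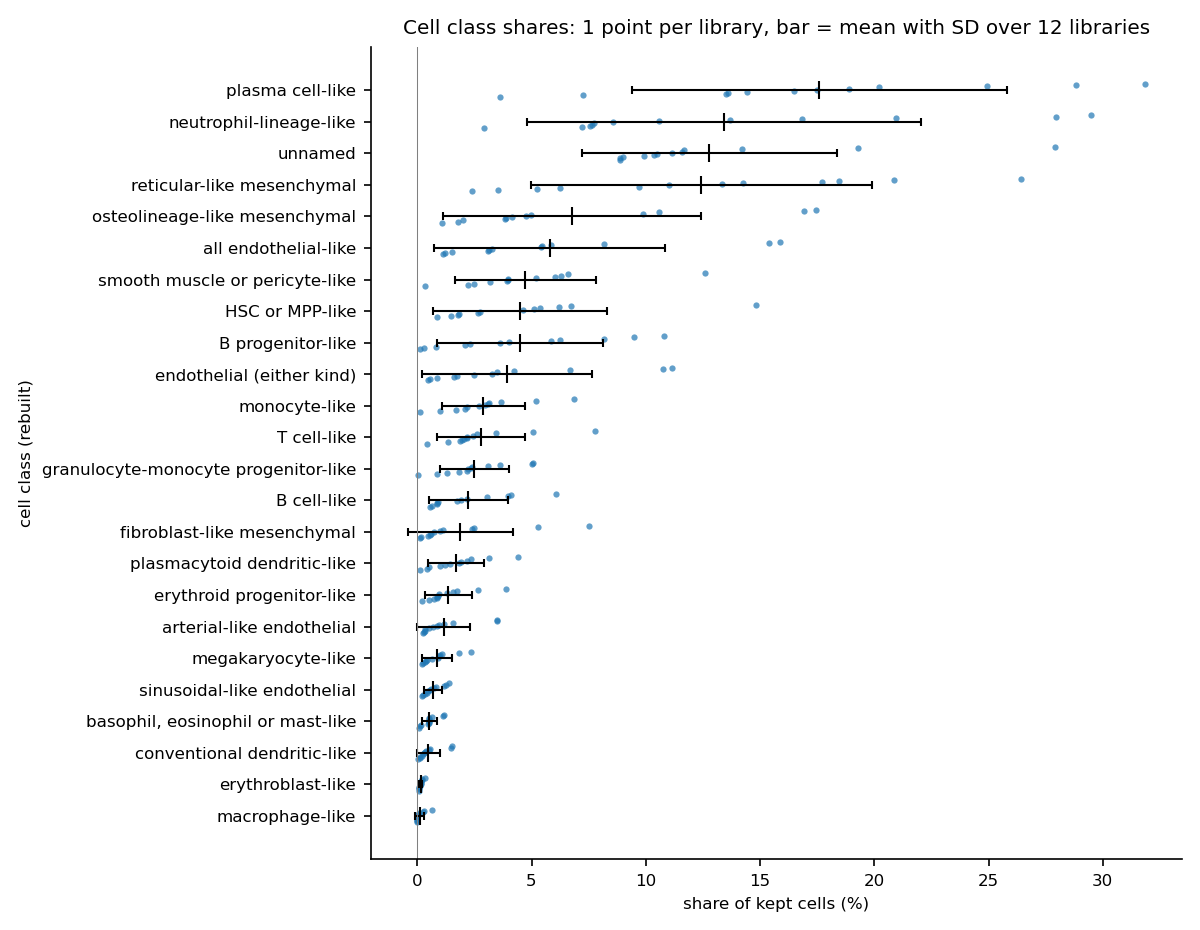
Share of kept cells (%) in each rebuilt cell class, with 1 point per library and a bar at the mean with the SD over 12 libraries. Plasma cell-like cells had the highest mean share (17.6%) and macrophage-like cells the lowest (0.108%). Erythroblast-like cells lay below macrophage-like cells without library correction (0.241% against 0.344%) and without doublet removal (0.330% against 0.347%).

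Some named clusters had stress response or immune genes among their 10 leading genes, which was not tested. A reticular-like cluster of 3307 cells had PTGS2, LIF and HMOX1 among them. An HSC or MPP-like cluster of 340 cells had HSPA1A, HSPA1B and JUN. A further HSC or MPP-like cluster of 2023 cells, led by AVP, also had the chemokine genes CXCL2 and CXCL3. A mural cluster of 2552 cells had the metallothionein gene MT1A and the chemokine gene CCL8. Both fibroblast-like clusters drew 39.1% and 40.98% of their cells from a single library.

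The niche list holds 17 cytokine and adhesion genes through which marrow stroma acts on blood stem and progenitor cells, and 5 of them had their highest mean level in reticular-like cells. CXCL12, the chemokine that retains stem cells in the marrow, reached 5428 ± 2270.3 CPM there (SD, n = 12), against background levels of 56.5 in T cell-like and 8.31 in plasma cell-like cells. KITLG, the ligand of the receptor KIT, reached 387 ± 154 CPM (0.618 in T cell-like and 0.325 in plasma cell-like cells). ANGPT1, a ligand of the receptor TEK, reached 768 ± 331 CPM (1.89 in T cell-like and 0.964 in plasma cell-like cells). IL7, a growth factor of lymphoid progenitors, stood at 158 ± 66.2 CPM (3.89 in T cell-like and 1.42 in plasma cell-like cells) and the adhesion gene VCAM1 at 888 ± 384 CPM (3.26 in T cell-like and 0.725 in plasma cell-like cells). Other niche genes peaked elsewhere. IGF1 was highest in fibroblast-like cells (495 ± 399 CPM, n = 10, with 94.0 in plasma cell-like cells). IL6 was highest in mural cells (235 ± 135 CPM, n = 12, with 1.44 in plasma cell-like cells). BMP6 was highest in sinusoidal-like endothelial cells (189.9 ± 88.1 CPM, n = 11). BMP6 also reached 159 CPM in plasma cell-like and 160.2 CPM in HSC or MPP-like cells. CSF1 (241 ± 106 CPM) and LIF (86.1 ± 84.6 CPM) were highest in basophil, eosinophil or mast-like cells (n = 9), and FLT3LG in T cell-like cells (52.4 ± 13.1 CPM, n = 12). In reticular-like cells CSF1 was at 174 ± 74.4 CPM. These highest classes are by mean level, and the order of classes was tested only in the pairs below.

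**Figure D2:**
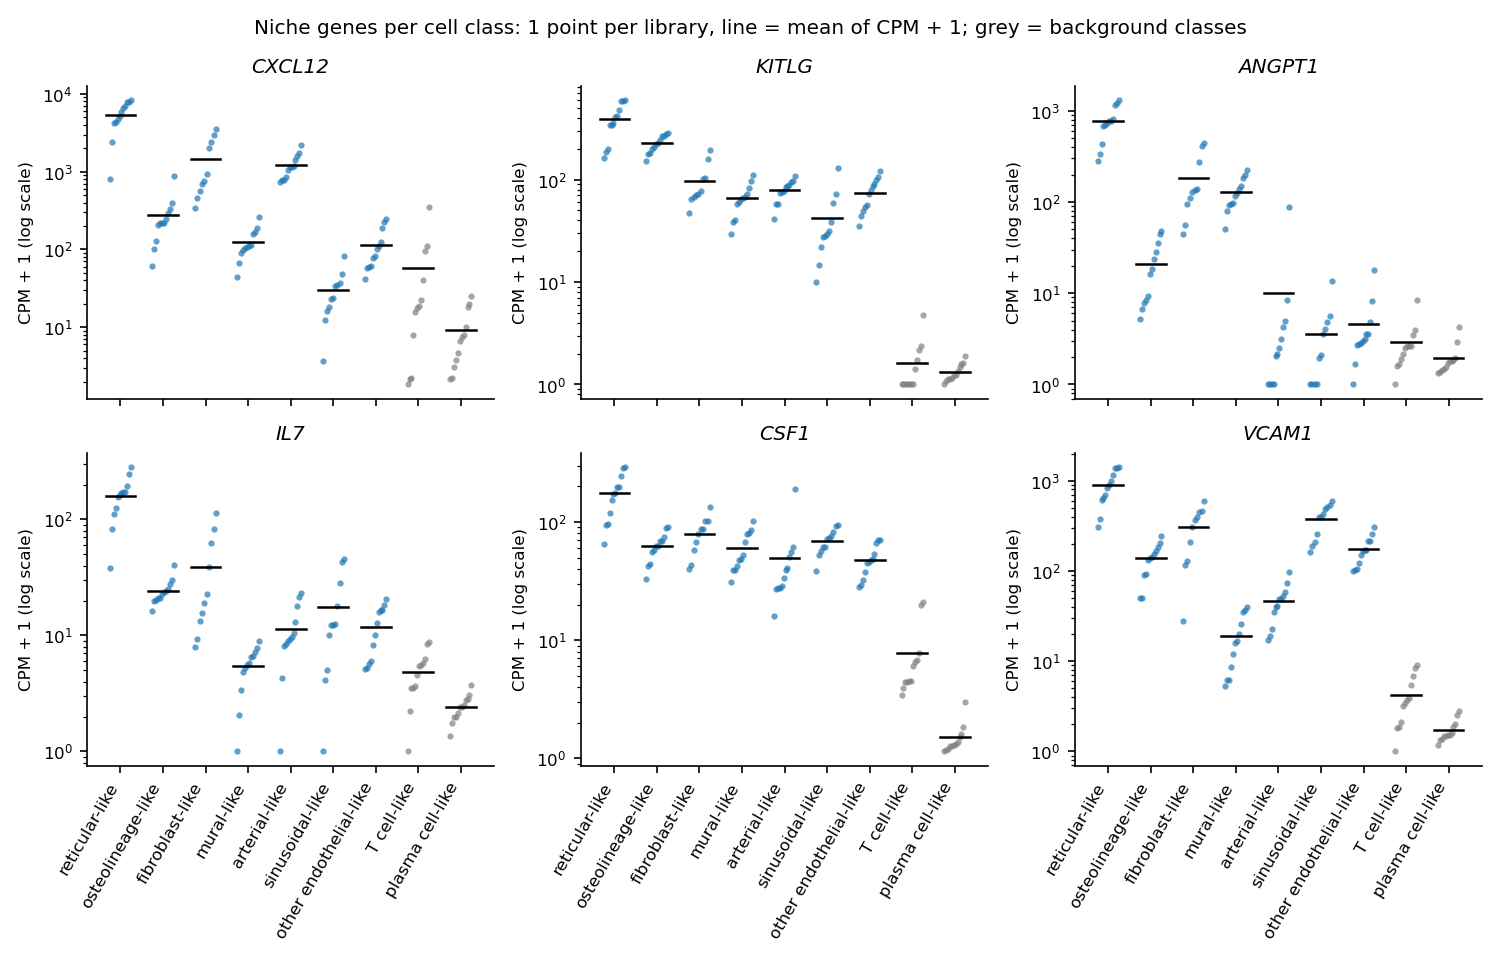
Levels of 6 niche genes (CPM + 1 on a log scale) per cell class, with 1 point per library with at least 20 cells of the class and a line at the mean of CPM + 1; grey points are the T cell-like and plasma cell-like background. CXCL12 had a mean of 5428 CPM in reticular-like cells and 8.31 CPM in plasma cell-like cells.

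Reticular-like cells were first set against all endothelial-like cells of the same library, to ask which signals each side of the niche carries (12 library pairs, 12018 against 5635 cells). Reticular-like cells carried far more RNA of CXCL12, KITLG, ANGPT1 and IL7 and of the lipid-linked genes APOE and CFD. Endothelial-like cells carried more of CSF3, the granulocyte growth factor, of BMP6, and of the vessel receptors and adhesion genes KDR, TEK, SELE and VWF. Of the matrix lists, 11 of 12 collagens and 16 of 23 proteoglycan and matricellular genes were higher in reticular-like cells, with 4 of the latter lower. All 5 list calls of this comparison were lost at adjusted p = 0.0952 to 0.262 with an estimated correlation. Of 10515 genes tested, 3567 were higher and 3295 lower in reticular-like cells, 1327 and 1092 of them by a log2 fold change of at least 1.

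Among the niche genes, 9 of the 16 tested were higher, 6 lower and 1 did not pass, and the list as a whole was not called (adjusted p = 0.259, adjusted p = 0.324 with an estimated correlation). CXCL12 (ENSG00000107562) had a log2 fold change of 4.12 ± 0.40 (SE; adjusted p = 3.47e-07), at 5428 ± 2270.3 against 298 ± 143 CPM (SD, n = 12). ANGPT1 (ENSG00000154188) had a log2 fold change of 7.57 ± 0.36 (SE; adjusted p = 1.02e-10). PTN (ENSG00000105894), a heparin-binding growth factor, had a log2 fold change of 7.18 ± 0.43 (SE; adjusted p = 1.42e-09). IL7 (ENSG00000104432), KITLG (ENSG00000049130), VCAM1 (ENSG00000162692) and CSF1 (ENSG00000184371) were higher by log2 fold changes of 3.52 ± 0.19, 2.39 ± 0.22, 2.05 ± 0.19 and 1.55 ± 0.14 (SE; adjusted p = 4.34e-10, 2.24e-07, 2.32e-07 and 1.10e-07). On the endothelial side, CSF3 (ENSG00000108342) had a log2 fold change of -8.30 ± 0.33 (SE; adjusted p = 1.60e-11), at 0.0368 ± 0.0640 against 21.5 ± 15.5 CPM. BMP6 (ENSG00000153162) had a log2 fold change of -5.79 ± 0.44 (SE; adjusted p = 2.37e-08). In this and the later comparisons, the genes named passed an adjusted p of 0.05 and had 1 direction in every library pair, except where a count of pairs is given.

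Fibrillar and associated collagens were called higher (11 higher, 0 lower, 1 not passing, adjusted p = 1.44e-06, adjusted p = 0.167 with an estimated correlation). So were proteoglycans and matricellular proteins (16 higher, 4 lower, 3 not passing, adjusted p = 0.00369, adjusted p = 0.226 with an estimated correlation), led by DCN (ENSG00000011465) and FBLN1 (ENSG00000077942) (log2 fold change 7.33 ± 0.35 and 7.27 ± 0.25, SE). POSTN (ENSG00000133110) and the elastin gene ELN (ENSG00000049540) were lower (-3.16 ± 0.48 and -2.72 ± 0.27). Endothelial adhesion genes were called lower (0 higher, 8 lower, 1 not passing, adjusted p = 0.00120, adjusted p = 0.0952 with an estimated correlation). Of these, SELE (ENSG00000007908), which captures rolling leukocytes, was at 0.536 ± 0.547 against 704 ± 339.7 CPM with a log2 fold change of -10.34 ± 0.27 (SE; adjusted p = 4.27e-13), and VWF (ENSG00000110799), von Willebrand factor, had -8.85 ± 0.24. The VEGF, angiopoietin and PDGF list was also called lower (6 higher, 14 lower, 1 not passing, adjusted p = 0.0418, adjusted p = 0.167 with an estimated correlation). It divided by side. The vessel receptors KDR (ENSG00000128052) and TEK (ENSG00000120156) were lower (-9.59 ± 0.23 and -9.16 ± 0.25), while FGF7 (ENSG00000140285) and the stromal receptor PDGFRB (ENSG00000113721) were higher (7.13 ± 0.27 and 7.13 ± 0.29). Interferon and antigen presentation genes were called lower (1 higher, 13 lower, 4 not passing, adjusted p = 0.00362, adjusted p = 0.262 with an estimated correlation). Of 78 ribosomal protein genes, 1 was higher and 75 were lower (median log2 fold change -1.23).

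The adipocyte and lipid list was not called (13 higher, 6 lower, 2 not passing, adjusted p = 0.0733, adjusted p = 0.309 with an estimated correlation). It held APOE (ENSG00000130203) and CFD (ENSG00000197766), a complement factor made by fat cells, at 4565 and 3190.3 CPM in reticular-like cells (log2 fold change 7.97 ± 0.42 and 7.95 ± 0.43). The fatty-acid carriers FABP4 (ENSG00000170323) and CD36 (ENSG00000135218) stood at 2674 and 1142 CPM in endothelial-like cells (-5.32 ± 0.43 and -4.40 ± 0.57). Notch pathway genes counted 3 higher, 8 lower, 0 not passing, adjusted p = 0.0524, adjusted p = 0.262 with an estimated correlation. Immediate-early and dissociation genes counted 10 higher, 4 lower, 5 not passing, adjusted p = 0.146, adjusted p = 0.677 with an estimated correlation. Outside the lists, the rule named the sphingosine phosphate receptor gene S1PR3 (ENSG00000213694) (7.95 ± 0.21), the antisense RNA gene CHL1-AS1 (ENSG00000234661) and C9orf47 (ENSG00000186354) on the reticular side. It named MPZL2 (ENSG00000149573) (-9.39 ± 0.27), GIMAP5 (ENSG00000196329) (-8.48 ± 0.21) and NOVA2 (ENSG00000104967) (-8.25 ± 0.31) on the endothelial side, with adjusted p from 3.24e-13 to 1.16e-11. Endothelial-like cells had 1 UMI of CHL1-AS1 and 3 UMIs of C9orf47 in all, ratios of CPM of 1149 (95% counting interval 206 to 45385) and 655 (95% counting interval 224 to 3177). RefSeq names list C9orf47 under S1PR3, so that pair is 1 locus. The other lists were not called (adjusted p from 0.0627 to 0.602, from 0.262 to 0.690 with an estimated correlation). Adjusted over the list alone, the counts were the same except for 8 lower of TGF-beta and BMP response genes (6 over all genes), 11 higher of immediate-early genes and 3 higher of hypoxia and glycolysis genes. 

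Osteolineage-like cells were set against reticular-like cells to ask how niche and matrix genes divide between bone-lining and marrow stroma (12 pairs, 6548 against 12018 cells). Osteolineage-like cells had less RNA of every one of the 6 core niche genes, from KITLG, with the smallest difference, to ANGPT1, with the largest. They had more of WIF1, which blocks WNT ligands, of ENPP1 and MMP13, which act in mineral and matrix turnover, and of BMP6. Of 10507 genes tested, 2911 were higher and 2555 lower, 614 and 571 of them by a log2 fold change of at least 1. The majority turned with every gene with at least 1 count (3041 higher and 3947 lower).

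Niche genes were called lower (3 higher, 11 lower, 1 not passing, adjusted p = 0.00173, adjusted p = 0.147 with an estimated correlation). ANGPT1 had a log2 fold change of -5.35 ± 0.31 (SE; adjusted p = 3.10e-09), at 20.02 ± 15.1 against 768 ± 331 CPM (SD, n = 12). CXCL12 had a log2 fold change of -4.39 ± 0.24 (SE; adjusted p = 1.33e-09), at 276 ± 216 against 5428 ± 2270.3 CPM. VCAM1, IL7 and CSF1 were lower by log2 fold changes of -2.67 ± 0.21, -2.60 ± 0.21 and -1.35 ± 0.19 (SE; adjusted p = 6.53e-08, 6.68e-08 and 1.87e-05). KITLG had a log2 fold change of -0.65 ± 0.16 (SE; adjusted p = 0.00262) and was lower in 10 of 12 pairs, so osteolineage-like cells kept 225 CPM of it. BMP6 and BMP4 (ENSG00000125378) were higher (2.70 ± 0.34 and 1.27 ± 0.15; adjusted p = 8.35e-06 and 4.44e-06; 11 and 12 of 12 pairs). Chemokines were also called lower (1 higher, 5 lower, 2 not passing, adjusted p = 0.00620, adjusted p = 0.194 with an estimated correlation), as were basement membrane genes (2 higher, 12 lower, 0 not passing, adjusted p = 2.12e-05, adjusted p = 0.147 with an estimated correlation).

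Adipocyte and lipid genes were called lower (2 higher, 15 lower, 3 not passing, adjusted p = 2.12e-05, adjusted p = 0.147 with an estimated correlation). The lipid droplet gene PLIN1 (ENSG00000166819) and the adipogenic regulator CEBPA (ENSG00000245848) were lower (-4.35 ± 0.38 and -4.06 ± 0.16), and ADIRF (ENSG00000148671) was higher (2.66 ± 0.29). CD36 had a log2 fold change of 1.14 ± 0.43 (SE; adjusted p = 0.0347), higher in 10 of 12 pairs. Interferon genes (0 higher, 16 lower, 2 not passing, adjusted p = 1.28e-05, adjusted p = 0.147 with an estimated correlation) were called lower. Immediate-early genes were likewise called lower (2 higher, 12 lower, 5 not passing, adjusted p = 0.00315, adjusted p = 0.515 with an estimated correlation). Oxidative phosphorylation genes, of the respiratory chain, were called higher (15 higher, 0 lower, 3 not passing, adjusted p = 2.18e-04, adjusted p = 0.421 with an estimated correlation). Beside them, 76 of 78 ribosomal protein genes were higher and 0 lower (median log2 fold change 1.38). Fibrillar and associated collagens went both ways (4 higher, 6 lower, 2 not passing, adjusted p = 0.434, adjusted p = 0.718 with an estimated correlation). COL8A1 (ENSG00000144810) and COL12A1 (ENSG00000111799) were higher (1.75 ± 0.24, 11 of 12 pairs, and 1.70 ± 0.12), and COL14A1 (ENSG00000187955) and COL6A3 (ENSG00000163359) lower (-5.54 ± 0.33 and -2.64 ± 0.26).

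Bone remodelling and mineralisation genes counted 5 higher, 2 lower, 2 not passing, adjusted p = 0.150, adjusted p = 0.261 with an estimated correlation. Of these, ENPP1 (ENSG00000197594), which makes pyrophosphate, had a log2 fold change of 4.78 ± 0.27 (SE; adjusted p = 2.56e-09), at 415 ± 155 against 17.9 ± 13.1 CPM. The collagenase MMP13 (ENSG00000137745) had 4.08 ± 0.50 (11 of 12 pairs) and the membrane protease MMP14 (ENSG00000157227) -1.02 ± 0.09. WNT and BMP modulators counted 4 higher, 5 lower, 6 not passing, adjusted p = 0.672, adjusted p = 0.718 with an estimated correlation. WIF1 (ENSG00000156076) had a log2 fold change of 7.04 ± 0.57 (SE; adjusted p = 7.66e-08), at 1353 ± 350.2 against 27.2 ± 44.8 CPM. The BMP antagonist NOG (ENSG00000183691) had 2.99 ± 0.36. CHRDL1 (ENSG00000101938), a BMP antagonist, and FRZB (ENSG00000162998), a WNT antagonist, were lower (-5.67 ± 0.30 and -4.09 ± 0.31). Outside the lists, SLC36A2 (ENSG00000186335), CHST13 (ENSG00000180767) and the kallikrein gene KLK1 (ENSG00000167748) were highest above reticular-like cells (7.55 ± 0.30, 7.01 ± 0.27 and 6.78 ± 0.41). CPXM1 (ENSG00000088882), FREM1 (ENSG00000164946) and SLC7A10 (ENSG00000130876) were lowest (-6.17 ± 0.26, -5.64 ± 0.27 and -4.63 ± 0.30), with adjusted p from 1.15e-10 to 7.69e-09. The other lists were not called (adjusted p from 0.0585 to 0.738, from 0.148 to 0.842 with an estimated correlation). Adjusted over the list alone, the counts were the same except for 6 lower of chemokines and 16 lower of adipocyte genes. The chemokine and immediate-early calls were lost without library correction (adjusted p = 0.0585 and 0.0679) and without the reticular-like cluster led by PTGS2 and LIF (adjusted p = 0.237 and 0.956). CD36 lost its call without the replicate block, without library correction and without that cluster (log2 fold change 0.54, 0.78 and 0.93), and without any 1 of replicates 2, 3, 6, 7, 9 and 11 (0.91 to 1.14).

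Fibroblast-like cells were set against reticular-like cells in 10 libraries (1802 against 11343 cells), since replicates 7 and 8 had fewer than 20 fibroblast-like cells. Fibroblast-like cells had more RNA of the growth factor IGF1 and less of CXCL12, KITLG, ANGPT1, IL7, VCAM1 and CSF1. Of the lists, 10 of 12 collagens, 15 of 23 proteoglycan and matricellular genes and 18 of 18 respiratory chain genes were higher, and 13 of 21 adipocyte genes lower. All 5 list calls of this comparison were lost at adjusted p = 0.0852 to 0.534 with an estimated correlation. Of 10807 genes tested, 2368 were higher and 1912 lower, 488 and 603 of them by a log2 fold change of at least 1. With every gene with at least 1 count, 1969 were higher and 2313 lower, so the majority turned.

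Niche genes counted 2 higher, 7 lower, 6 not passing, adjusted p = 0.354, adjusted p = 0.634 with an estimated correlation. CXCL12 had a log2 fold change of -1.90 ± 0.25 (SE; adjusted p = 2.59e-04), at 1466 ± 1159.8 against 5296 ± 2453 CPM (SD, n = 10). IL7 and ANGPT1 were lower by log2 fold changes of -2.19 ± 0.25 and -2.02 ± 0.27 (SE; adjusted p = 2.59e-04 and 2.69e-04). KITLG and VCAM1 were lower by -1.73 ± 0.24 and -1.46 ± 0.27 (adjusted p = 3.17e-04 and 0.00127), in 10 of 10 pairs each. CSF1 had a log2 fold change of -0.83 ± 0.26 (SE; adjusted p = 0.0223) and was lower in 8 of 10 pairs. IGF1 (ENSG00000017427) had a log2 fold change of 2.12 ± 0.37 (SE; adjusted p = 9.13e-04) and was higher in 9 of 10 pairs.

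Fibrillar and associated collagens were called higher (10 higher, 0 lower, 2 not passing, adjusted p = 7.26e-07, adjusted p = 0.0852 with an estimated correlation). COL1A1 (ENSG00000108821), the main collagen of bone and tendon, was at 2105 ± 1956 against 521 ± 282 CPM, with log2 fold changes of 1.95 ± 0.24 for COL1A1 and 1.86 ± 0.22 for COL6A3. Proteoglycans and matricellular proteins were called higher (15 higher, 0 lower, 8 not passing, adjusted p = 8.29e-06, adjusted p = 0.0852 with an estimated correlation). The rule named OGN (ENSG00000106809) (4.09 ± 0.62) and POSTN (2.70 ± 0.81, higher in 8 of 10 pairs). Oxidative phosphorylation genes were called higher (18 higher, 0 lower, 0 not passing, adjusted p = 2.15e-10, adjusted p = 0.182 with an estimated correlation). Of 78 ribosomal protein genes, 78 were higher and 0 lower as well (median log2 fold change 1.05). So were hypoxia and glycolysis genes (8 higher, 2 lower, 6 not passing, adjusted p = 0.0127, adjusted p = 0.534 with an estimated correlation). Adipocyte and lipid genes were called lower (0 higher, 13 lower, 8 not passing, adjusted p = 5.09e-04, adjusted p = 0.182 with an estimated correlation). None of the 11 chemokines tested passed with edgeR (at an unadjusted p under 0.05, 1 gene, while DESeq2's Wald test called 1 higher and 2 lower).

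WNT and BMP modulators counted 4 higher, 4 lower, 8 not passing, adjusted p = 0.468, adjusted p = 0.634 with an estimated correlation. SFRP2 (ENSG00000145423), which binds WNT ligands, had a log2 fold change of 4.47 ± 0.98 (SE; adjusted p = 0.00357) and was higher in 9 of 10 pairs. DKK3 (ENSG00000050165) had a log2 fold change of 2.98 ± 0.54 (SE; adjusted p = 0.00113). BMP5 (ENSG00000112175) and FRZB were lower (-3.28 ± 0.64 and -2.34 ± 0.54). Outside the lists, the retinol carrier RBP4 (ENSG00000138207) and ECM1 (ENSG00000143369) were among the genes named as higher (4.32 ± 0.76, in 8 of 10 pairs, and 4.22 ± 0.65). ACER2 (ENSG00000177076) and RTKN2 (ENSG00000182010) were among those named as lower (-2.85 ± 0.30 and -2.64 ± 0.32), with adjusted p from 2.59e-04 to 0.00142. The other lists were not called (adjusted p from 0.354 to 0.975, from 0.634 to 0.974 with an estimated correlation). Adjusted over the list alone, the counts differed for 6 lists, with 11 collagens higher, 14 adipocyte genes lower, 9 hypoxia genes higher and 1 receptor gene lower. There were also 6 TGF-beta genes higher (4 over all genes), and 0 interferon genes higher and 1 lower (1 and 3 over all genes). The hypoxia and glycolysis call was lost without library correction (adjusted p = 0.113) and with low-UMI clusters kept in their class (adjusted p = 0.124). IGF1, POSTN, SFRP2 and RBP4 lost their calls without the replicate block (log2 fold change 1.56, 2.30, 1.80 and 2.63), and CSF1 with a minimum of 50 cells (-0.64).

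Mural cells were set against reticular-like cells to ask which niche and vessel signals each perivascular class carries (12 pairs, 4321 against 12018 cells). Mural cells had more RNA of IL6, PDGFA and PDGFB and less of CXCL12, VCAM1, IL7, KITLG, ANGPT1, CSF1 and PDGFRA. In mural cells, 7 of 9 Notch pathway genes and 18 of 18 respiratory chain genes were higher, and 11 of 12 fibrillar collagens lower. All 7 list calls of this comparison were lost at adjusted p = 0.117 to 0.393 with an estimated correlation. Of 10557 genes tested, 3656 were higher and 3277 lower, 1360 and 1114 of them by a log2 fold change of at least 1. The majority turned with DESeq2 size factors (3323 higher and 3667 lower), with the DESeq2 Wald test (3423 and 3747) and with every gene with at least 1 count (4301 and 5015).

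Niche genes were called lower (2 higher, 11 lower, 1 not passing, adjusted p = 0.00687, adjusted p = 0.117 with an estimated correlation). VCAM1 had a log2 fold change of -5.54 ± 0.45 (SE; adjusted p = 5.25e-08), at 18.002 ± 12.5 against 888 ± 384 CPM (SD, n = 12). CXCL12 had a log2 fold change of -5.19 ± 0.39 (SE; adjusted p = 2.16e-08), at 125 ± 59.1 against 5428 ± 2270.3 CPM. IL7, KITLG, ANGPT1 and CSF1 were lower by log2 fold changes of -4.65 ± 0.28, -2.30 ± 0.26, -2.30 ± 0.28 and -1.24 ± 0.25 (SE; adjusted p = 1.60e-09, 1.38e-06, 4.35e-06 and 4.13e-04), CSF1 in 11 of 12 pairs and the others in 12 of 12. IGF1 fell to 0.885 CPM (-6.75 ± 0.39). IL6 (ENSG00000136244), an inflammatory and haematopoietic cytokine, had a log2 fold change of 3.36 ± 0.59 (SE; adjusted p = 1.27e-04) and was higher in 11 of 12 pairs.

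Notch pathway genes were called higher (7 higher, 1 lower, 1 not passing, adjusted p = 0.009998, adjusted p = 0.192 with an estimated correlation). The Notch target NRARP (ENSG00000198435) had a log2 fold change of 7.98 ± 0.37 (SE; adjusted p = 7.92e-11), at 145 ± 57.4 against 0.833 ± 0.584 CPM. HES4 (ENSG00000188290) had 2.57 ± 0.20, while the receptor NOTCH2 (ENSG00000134250) was lower (-1.80 ± 0.13). Fibrillar collagens were called lower (0 higher, 11 lower, 1 not passing, adjusted p = 1.54e-05, adjusted p = 0.192 with an estimated correlation). Proteoglycans and matricellular proteins were too (4 higher, 15 lower, 4 not passing, adjusted p = 0.00329, adjusted p = 0.117 with an estimated correlation). Oxidative phosphorylation genes were called higher (18 higher, 0 lower, 0 not passing, adjusted p = 1.57e-07, adjusted p = 0.372 with an estimated correlation). Beside them, 76 of 78 ribosomal protein genes were higher and 0 lower (median log2 fold change 1.58). Adipocyte and lipid genes (3 higher, 12 lower, 6 not passing, adjusted p = 0.0469, adjusted p = 0.393 with an estimated correlation) were called lower. Interferon genes were called lower as well (2 higher, 11 lower, 5 not passing, adjusted p = 0.0467, adjusted p = 0.393 with an estimated correlation). In the adipocyte list, ADIRF and FABP4 were higher (4.80 ± 0.47 and 2.80 ± 0.31) and CFD and PLIN1 lower (-6.72 ± 0.40 and -5.60 ± 0.31).

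Basement membrane genes split evenly (7 higher, 7 lower, 0 not passing, adjusted p = 0.903, adjusted p = 0.921 with an estimated correlation). LAMA5 (ENSG00000130702) and COL4A2 (ENSG00000134871) were higher (4.17 ± 0.20 and 2.25 ± 0.18), and LAMB1 (ENSG00000091136) and COL15A1 (ENSG00000204291) lower (-4.24 ± 0.37 and -3.91 ± 0.43). The VEGF, angiopoietin and PDGF list counted 6 higher, 7 lower, 3 not passing, adjusted p = 0.903, adjusted p = 0.921 with an estimated correlation. The ligands PDGFB (ENSG00000100311) and PDGFA (ENSG00000197461) had log2 fold changes of 8.98 ± 0.28 and 5.07 ± 0.20 (adjusted p = 1.64e-12 and 1.78e-11). The receptor PDGFRA (ENSG00000134853) and the lymphatic growth factor VEGFC (ENSG00000150630) had -7.41 ± 0.39 and -7.20 ± 0.45 (adjusted p = 3.92e-10 and 2.23e-09). Outside the lists, OR51E1 (ENSG00000180785), GPR20 (ENSG00000204882) and the neurotrophin gene NTF3 (ENSG00000185652) were highest above reticular-like cells (9.90 ± 0.29, 9.48 ± 0.35 and 9.01 ± 0.30). GDF10 (ENSG00000266524) and the gap junction gene GJA1 (ENSG00000152661) were lower (-7.20 ± 0.33 and -7.07 ± 0.36), with adjusted p from 7.20e-13 to 2.13e-10. CHL1-AS1 was also named as lower, with 0 UMIs in mural cells, so that it was at least 284-fold lower than in reticular-like cells, against a floor of 3 UMIs over the class. The other lists were not called (adjusted p from 0.0549 to 0.822, from 0.372 to 0.921 with an estimated correlation). Adjusted over the list alone, the counts were the same except for 13 lower of adipocyte genes. The adipocyte and interferon calls were lost with a minimum of 50 cells, with the stricter cell filter and without the reticular-like cluster led by PTGS2 and LIF, and the adipocyte call also with DESeq2 size factors (adjusted p = 0.0512 to 0.207 over these settings).

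Within the endothelium, arterial-like cells were set against sinusoidal-like cells in 11 libraries (1053 against 634 cells), since replicate 7 had fewer than 20 sinusoidal-like cells. The 3858 endothelial-like cells of unresolved clusters (over 12 libraries), in neither class, did not enter. Arterial-like cells had more RNA of CXCL12, of the Notch ligand JAG2 and of VEGFC and FGF2, and sinusoidal-like cells more of VCAM1, SELE, ICAM1, NRP2 and NRP1. In arterial-like cells, 16 of 18 interferon response genes were higher, and 7 of 11 adipocyte and 14 of 19 immediate-early genes lower. All 5 list calls of this comparison were lost at adjusted p = 0.283 with an estimated correlation. Of 4776 genes tested, fewer than for the other pairs because the cells were few, 1440 were higher and 1117 lower in arterial-like cells, 320 and 382 of them by a log2 fold change of at least 1. The majority turned with every gene with at least 1 count (1823 higher and 1968 lower), a minimum of 50 cells (670 and 781) and low-UMI clusters kept in their class (991 and 1019). It also turned with the unresolved endothelial clusters counted as sinusoidal (1066 and 1103), where 1459 of the 2557 genes were called, 25 of them with the opposite direction.

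CXCL12 had a log2 fold change of 5.33 ± 0.29 (SE; adjusted p = 5.11e-11), at 1224 ± 466.4 against 29.2 ± 21.3 CPM (SD, n = 11), in 11 of 11 pairs. VCAM1 had a log2 fold change of -3.03 ± 0.25 (SE; adjusted p = 1.16e-08), at 47.2 ± 22.7 against 378 ± 152 CPM. IL15 (ENSG00000164136) had a log2 fold change of -1.71 ± 0.19 (SE; adjusted p = 7.06e-07), in 11 of 11 pairs. KITLG had a log2 fold change of 1.002 ± 0.29 (SE; adjusted p = 0.00658), higher in 9 of 11 pairs. CSF1 had a log2 fold change of -0.86 ± 0.25 (SE; adjusted p = 0.00792), lower in 9 of 11 pairs. ANGPT1 and IL7 had too few counts in both classes to be tested. The niche list was not called (2 higher, 3 lower, 2 not passing, adjusted p = 0.765, adjusted p = 0.769 with an estimated correlation). Interferon and antigen presentation genes were called higher (16 higher, 0 lower, 2 not passing, adjusted p = 4.13e-07, adjusted p = 0.283 with an estimated correlation). Oxidative phosphorylation genes were called higher too (16 higher, 0 lower, 1 not passing, adjusted p = 1.13e-04, adjusted p = 0.283 with an estimated correlation). Of 77 ribosomal protein genes, 70 were higher and 0 lower as well (median log2 fold change 0.57). Proteoglycans and matricellular proteins were called higher (9 higher, 3 lower, 2 not passing, adjusted p = 0.0239, adjusted p = 0.283 with an estimated correlation). Adipocyte and lipid genes were called lower in arterial-like cells (0 higher, 7 lower, 4 not passing, adjusted p = 0.00300, adjusted p = 0.283 with an estimated correlation). Immediate-early genes were called lower (0 higher, 14 lower, 5 not passing, adjusted p = 0.00144, adjusted p = 0.283 with an estimated correlation).

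Notch pathway genes counted 5 higher, 2 lower, 2 not passing, adjusted p = 0.186, adjusted p = 0.563 with an estimated correlation. HES4 and JAG2 (ENSG00000184916) were higher (4.24 ± 0.26 and 4.22 ± 0.22) and DLL1 (ENSG00000198719) and HES1 (ENSG00000114315) lower (-2.55 ± 0.26 and -1.15 ± 0.17, the latter in 10 of 11 pairs). Basement membrane genes counted 3 higher, 5 lower, 2 not passing, adjusted p = 0.697, adjusted p = 0.769 with an estimated correlation. LAMA5 and COL18A1 (ENSG00000182871) were higher (2.07 ± 0.24 and 1.36 ± 0.18) and NID1 (ENSG00000116962) and LAMA4 (ENSG00000112769) lower (-3.25 ± 0.22 and -2.21 ± 0.22). The VEGF, angiopoietin and PDGF list counted 6 higher, 6 lower, 2 not passing, adjusted p = 0.920, adjusted p = 0.909 with an estimated correlation. VEGFC and FGF2 (ENSG00000138685) were higher (4.38 ± 0.38 and 4.31 ± 0.44) and the co-receptors NRP2 (ENSG00000118257) and NRP1 (ENSG00000099250) lower (-5.69 ± 0.30 and -2.01 ± 0.19). Endothelial adhesion genes counted 3 higher, 3 lower, 1 not passing, adjusted p = 0.969, adjusted p = 0.973 with an estimated correlation. JAM2 (ENSG00000154721) and ALCAM (ENSG00000170017) were higher (3.93 ± 0.22 and 2.43 ± 0.38), and SELE, at 19.0 ± 41.4 against 999.7 ± 718 CPM, and ICAM1 (ENSG00000090339) lower (-6.79 ± 0.54 and -2.19 ± 0.12). Outside the lists, the rule named the transcription factor gene PRDM16 (ENSG00000142611), TMEM178A (ENSG00000152154) and PLLP (ENSG00000102934) as higher in arterial-like cells (5.88 ± 0.37 and 5.45 ± 0.37 for the last pair). It named FAM196B (ENSG00000204767), REEP1 (ENSG00000068615) and C1QTNF1 (ENSG00000173918) as lower (-4.95 ± 0.22 and -4.81 ± 0.28 for the last pair), with adjusted p from 1.71e-13 to 1.07e-09. Sinusoidal-like cells had 3 UMIs of PRDM16 and arterial-like cells 1 UMI of FAM196B in all, ratios of CPM of 410.4 (95% counting interval 140.2 to 1992) and 667 (95% counting interval 119 to 26389). The other lists were not called (adjusted p from 0.186 to 0.969, from 0.283 to 0.973 with an estimated correlation). Adjusted over the list alone, the counts were the same except for 4 lower of niche genes, 4 higher of basement membrane genes, 10 higher of proteoglycans, 8 lower of adipocyte genes and 5 lower of TGF-beta genes. With low-UMI clusters kept in their class, 0 of 18 oxidative phosphorylation genes passed and the call was lost (adjusted p = 0.398), and the proteoglycan call was lost without library correction or doublet removal (adjusted p = 0.0622 to 0.0650). KITLG lost its call with a minimum of 50 cells (3 libraries), without doublet removal and with unresolved endothelial clusters counted as sinusoidal (log2 fold change 0.28, 0.67 and 0.25), and CSF1 in the last setting (-0.43).

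HSC or MPP-like cells were set against GMP-like cells to ask how early progenitors differ from committed myeloid ones (11 pairs, 3952 against 2201 cells; replicate 1 had fewer than 20 GMP-like cells). HSC or MPP-like cells had more RNA of ANGPT1, CSF1 and IL15 from the niche list. Of these, CSF1 and IL15 were near background, at 7.72 and 7.85 CPM over 12 libraries. T cell-like and plasma cell-like cells had 6.75 and 0.504 CPM of CSF1, and 5.87 and 12.7 CPM of IL15. They had less of 20 of 20 cell cycle genes (6 lower and 3 higher without library correction) and more of 14 of 16 interferon response and 14 of 19 immediate-early genes. All 6 list calls of this comparison were lost at adjusted p = 0.266 to 0.288 with an estimated correlation. Of 10210 genes tested, 3872 were higher and 2941 lower, 974 and 362 of them by a log2 fold change of at least 1.

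Cell cycle genes were called lower (0 higher, 20 lower, 0 not passing, adjusted p = 1.38e-10, adjusted p = 0.266 with an estimated correlation). RRM2 (ENSG00000171848), a subunit of the enzyme that makes DNA precursors, had a log2 fold change of -3.90 ± 0.19 (SE; adjusted p = 3.42e-11), at 2.80 ± 1.52 against 45.6 ± 9.11 CPM (SD, n = 11). TOP2A (ENSG00000131747), a topoisomerase of dividing cells, had a log2 fold change of -3.85 ± 0.21 (SE; adjusted p = 1.20e-10). Of the 2204 GMP-like cells, 919 lay in a cluster led by replication genes. Interferon and antigen presentation genes were called higher (14 higher, 1 lower, 1 not passing, adjusted p = 3.99e-04, adjusted p = 0.266 with an estimated correlation). MX1 (ENSG00000157601) and BST2 (ENSG00000130303) were higher (1.85 ± 0.14 and 1.47 ± 0.09). Beside them, 74 of 78 ribosomal protein genes were higher and 1 lower (median log2 fold change 0.59). Immediate-early genes were called higher (14 higher, 0 lower, 5 not passing, adjusted p = 0.00111, adjusted p = 0.266 with an estimated correlation). BTG2 (ENSG00000159388), which restrains division, was at 176 ± 69.1 against 58.9 ± 28.5 CPM, with log2 fold changes of 1.86 ± 0.09 for BTG2 and 1.81 ± 0.13 for NR4A1 (ENSG00000123358). Niche genes were called higher (6 higher, 0 lower, 1 not passing, adjusted p = 0.0438, adjusted p = 0.266 with an estimated correlation). Chemokines were also called higher (4 higher, 0 lower, 0 not passing, adjusted p = 0.0438, adjusted p = 0.288 with an estimated correlation). The VEGF, angiopoietin and PDGF list was called higher (6 higher, 0 lower, 2 not passing, adjusted p = 0.0438, adjusted p = 0.266 with an estimated correlation).

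Haematopoietic receptors and integrins divided evenly (6 higher, 6 lower, 3 not passing, adjusted p = 0.867, adjusted p = 0.882 with an estimated correlation). FLT3 (ENSG00000122025) had a log2 fold change of 0.31 ± 0.07 (SE; adjusted p = 0.00109) within pairs at mean levels of 155 ± 50.6 against 148 ± 53.5 CPM. CSF3R (ENSG00000119535), the receptor of granulocyte colony-stimulating factor, had a log2 fold change of -0.73 ± 0.08 (SE; adjusted p = 3.71e-07), at 132 ± 21.3 against 265 ± 65.0 CPM. SELPLG (ENSG00000110876) was lower (-0.77 ± 0.13). Oxidative phosphorylation genes counted 10 higher, 3 lower, 5 not passing, adjusted p = 0.260, adjusted p = 0.880 with an estimated correlation. COX7C (ENSG00000127184) and ATP5PO (ENSG00000241837) were higher (0.66 ± 0.09 and 0.62 ± 0.07) and UQCRC1 (ENSG00000010256) lower (-0.65 ± 0.07). TGF-beta and BMP response genes counted 8 higher, 2 lower, 4 not passing, adjusted p = 0.109, adjusted p = 0.266 with an estimated correlation. Outside the lists, ZNF804B (ENSG00000182348), RASSF6 (ENSG00000169435) and CDH7 (ENSG00000081138) were highest in HSC or MPP-like cells (6.29 ± 0.25, 5.06 ± 0.25 and 4.30 ± 0.17). IQGAP3 (ENSG00000183856), CDCA3 (ENSG00000111665) and ESCO2 (ENSG00000171320), the last needed for sister chromatid cohesion, were lowest (-4.25 ± 0.24, -3.67 ± 0.29 and -3.58 ± 0.18), with adjusted p from 9.70e-12 to 6.00e-09. The other lists were not called (adjusted p from 0.0971 to 0.867, from 0.288 to 0.882 with an estimated correlation). Adjusted over the list alone, the counts were the same except for 4 higher of WNT and BMP modulators, 8 higher of the VEGF list and 1 lower of immediate-early genes. Without the cluster led by replication genes, 0 cell cycle genes were higher and 12 of 19 lower (adjusted p = 0.0806). Without library correction, 3 were higher and 6 lower (adjusted p = 0.167), with RRM2 and TOP2A at log2 fold changes of -0.36 and -0.31 and CDCA3 and ESCO2 at 0.129 and 0.103. The niche, chemokine and VEGF list calls were lost under several settings, among them no replicate block (adjusted p = 0.0524 to 0.167), and FLT3 lost its call without the block (0.30).

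**Figure D3:**
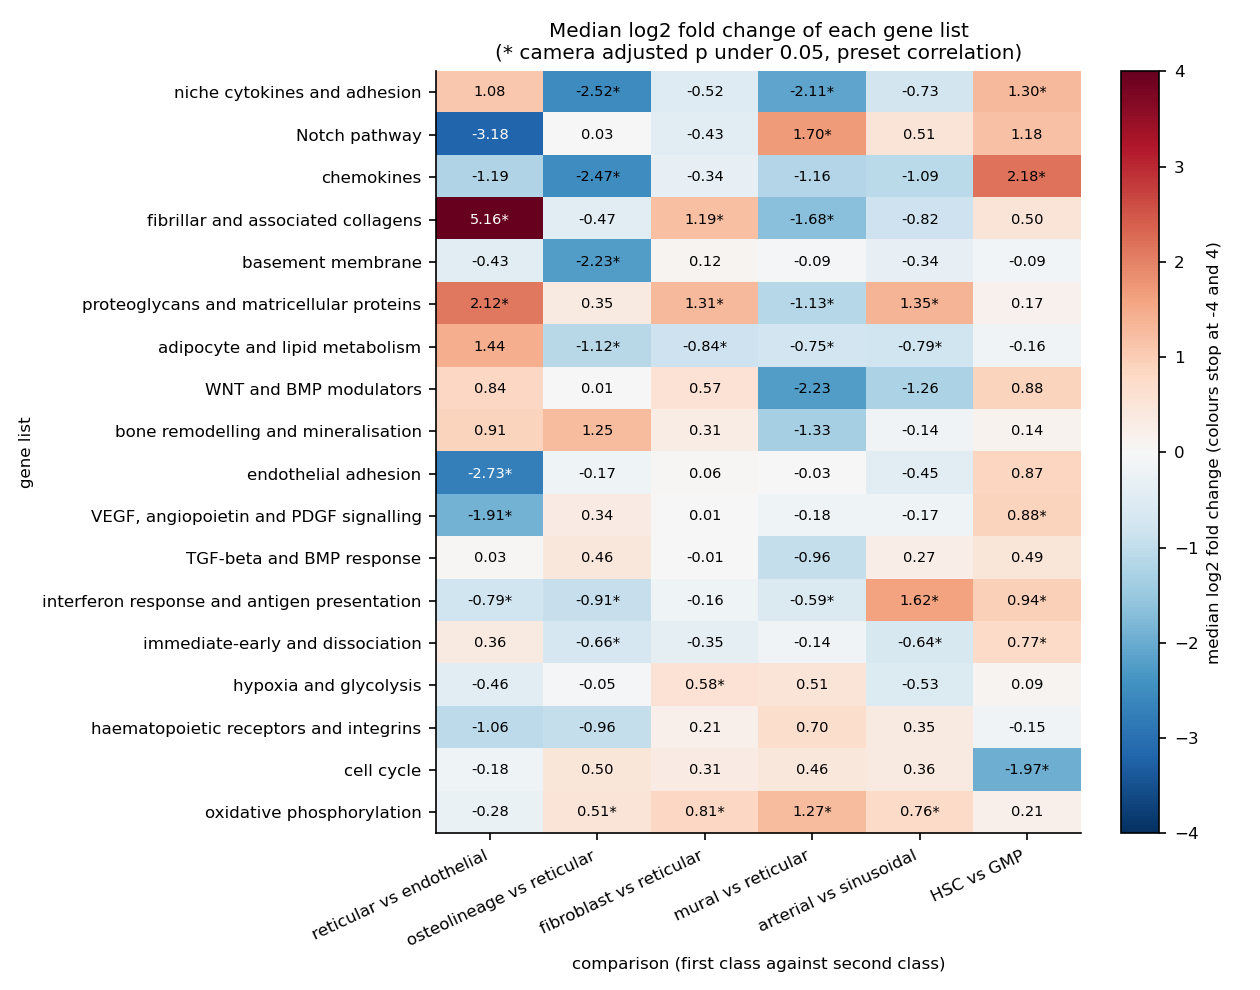
Median log2 fold change of each of the 18 gene lists (rows) in each of the 6 comparisons (columns, first class against second class); an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Oxidative phosphorylation genes had medians of 1.27 in mural and 0.81 in fibroblast-like against reticular-like cells.

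With an estimated correlation between genes, no list was called in any of the 6 comparisons. The median, the mean and the test did not all have the same sign for Notch pathway, WNT and BMP modulators and endothelial adhesion in osteolineage-like against reticular-like cells and for TGF-beta in fibroblast-like cells. The same held for basement membrane, immediate-early and haematopoietic receptor genes in mural cells, for VEGF signalling, haematopoietic receptors and cell cycle in arterial-like cells, and for bone remodelling in HSC or MPP-like cells. None of these was called.

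Immediate-early and dissociation genes, which respond to tissue digestion, were compared across libraries between classes. Their mean log2 CPM was 9.62 ± 0.50 in reticular-like, 9.30 ± 0.34 in endothelial-like and 7.42 ± 0.99 in HSC or MPP-like cells (SD, n = 12). Across the 12 libraries, reticular-like and endothelial-like levels had Pearson's r = 0.598 (permutation p = 0.0397; adjusted p = 0.119 over 3 relations) and Spearman's rho = 0.357 (p = 0.254; adjusted p = 0.763). Without the 2 libraries farthest from the median, r was 0.0544, so this relation rested largely on those libraries. With cell means, r was 0.631 (permutation p = 0.0287; adjusted p = 0.0861) and rho 0.552 (p = 0.0665; adjusted p = 0.199). There, r was 0.294 without the 2 farthest libraries. Reticular-like against HSC or MPP-like levels had r = 0.509 (permutation p = 0.108; adjusted p = 0.161) and rho = 0.168 (p = 0.606; adjusted p = 0.908), with r = 0.0653 without the 2 farthest libraries. Endothelial-like against HSC or MPP-like levels had r = 0.263 (permutation p = 0.369; adjusted p = 0.369) and rho = -0.0350 (p = 0.921; adjusted p = 0.921), with r = 0.335 without the 2 farthest. No relation passed the adjustment. Without replicate 1, r between reticular-like and HSC or MPP-like levels was -0.0465, and between endothelial-like and HSC or MPP-like levels -0.2499. The labels give no sequencing batches, so no relation was recomputed within batches.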

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

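The tests on KIT in reticular-like cells, and those on free RNA from endothelial-like, plasma cell-like and basophil, eosinophil or mast-like cells, were chosen after the levels were seen, and the other tests in this part before their results were seen. Of 39 sets of 4 to 10 libraries tested, 3 held a library set apart from the others by more than Dixon's 95% critical value, and chance gives this in about 1 in 20 groups. The log2 ratio of DKK3 (CPM + 1) in fibroblast-like over reticular-like cells was 6.19 in replicate 12 and 0.487 to 3.43 in the others (10 libraries in all). KIT in conventional dendritic-like cells was at 35.2 CPM in replicate 5 and at 10.3 to 20.5 CPM in the others (8 libraries in all). CXCL12 in megakaryocyte-like cells was at 60.6 CPM in replicate 12 and at 0.976 to 32.6 CPM in the others (10 libraries in all).

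In each comparison, the class labels were swapped within random sets of libraries, in 40 splits with the real labels included. The real labels alone gave a count as large as the real one, so 1 of 40 splits did in each of the 6 comparisons, the fewest that 40 splits can give. The classes were formed by clustering the same cells on their expression, so swapped labels had to give fewer genes. The test is therefore void, and whether chance can be excluded stays open for these counts. The real count and the highest of the other splits were 6862 and 2697 genes for reticular-like against endothelial-like cells, and 5466 and 3325 for osteolineage-like against reticular-like cells. They were 4280 and 1645 for fibroblast-like and 6933 and 4161 for mural against reticular-like cells. For arterial-like against sinusoidal-like cells they were 2557 and 0, and for HSC or MPP-like against GMP-like cells 6813 and 4832. The highest other splits swapped 1 to 3 libraries and left the real labels in the rest, and the median of the other splits was 0 genes.

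All 18 oxidative phosphorylation genes tested were higher in mural and in fibroblast-like cells than in reticular-like cells. The list median lay above that of 10000 lists matched on span and level. It did so by 0.677 in mural cells (1.27 against 0.596, central 95% from 0.202 to 1.01). In fibroblast-like cells it did so by 0.297 (0.814 against 0.517, from 0.187 to 0.776). Matched genes were drawn independently, while correlations estimated in the list were 0.775 in the mural and 0.428 in the fibroblast-like comparison. The central 95% may therefore be too narrow, so the test does not exclude that span and level give the rise. The 78 ribosomal protein genes, with short messages found outside the nucleus, had median log2 fold changes of 1.58 in mural (76 higher, 0 lower) and 1.05 in fibroblast-like cells (78 higher, 0 lower), as a larger share of nuclear RNA in reticular-like cells would give. That share may account for the pattern, and so might more RNA of both gene groups in the other classes, since no test here separates these. The libraries form 1 group, and no biological explanation was tested.

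Of the niche genes, 6 were higher in HSC or MPP-like than in GMP-like cells, among them ANGPT1 (118 against 36.5 CPM) and BMP6 (174 against 81.7). Free RNA would put a gene at the share of the source's level that other genes of the source reach. For this, 48 genes of reticular-like cells had a median share of 0.419% (highest 8.94%, IFITM3). ANGPT1 and IL15 lay above 100% of them, IL7 above 89.6% and CSF1 above 84.4%. Those 48 genes were picked for a low level in HSC or MPP-like against reticular-like cells. ANGPT1 and IL15, at 14.1% and 25.8%, therefore had to lie above nearly all of them. IL7 and CSF1, at 4.54% and 2.74%, lay within their range. The test therefore cannot decide on this source for these genes. Of the markers of other classes with a high level, NOV lay above 100% of 8 arterial-like ones (6.50% of the source's level). CSF1 lay above 87.5% of 8 of basophil, eosinophil or mast-like cells (2.39%). The share of NOV, above the highest arterial-like marker (FBLN5, 1.65%), argues against arterial-like cells as its source. The share of CSF1 lay within the range of the basophil, eosinophil or mast-like markers (highest CPA3, 5.93%). CSF1 also stood near its T cell-like background (7.72 against 6.75 CPM), so the test cannot decide on that source. BMP6 lay above 100% of 8 sinusoidal-like and 100% of 5 plasma cell-like markers (93.5% and 105%). Its levels in those classes, 189.9 and 159 CPM, were close to the 160.2 CPM of HSC or MPP-like cells. BMP6 therefore had to lie above nearly any marker, and the test decides nothing on its source. IL15, at 8.01% of its level in unresolved endothelial-like cells, lay above 77.8% of 9 markers, and free RNA of those cells could still be its source. Mixtures of sources were not tested, and no biological explanation was tested.

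KIT, the receptor of KITLG, stood at 120.3 ± 100.5 CPM in reticular-like cells, against 40.5 in HSC or MPP-like, 164 in erythroid progenitor-like and 418 in basophil, eosinophil or mast-like cells. Free RNA or doublets from the last 2 classes would also carry their markers. KIT reached 73.3% of its erythroid progenitor-like level, above 100% of 6 markers (highest APOC1, 31.5%). That level, 164 CPM, was not far above the reticular-like one, so KIT had to lie above nearly any marker. The test therefore decides nothing on erythroid progenitor-like cells as the source. For basophil, eosinophil or mast-like cells KIT reached 23.6%, above 100% of 8 markers (highest EPX, 0.235%). These last values argue against basophil, eosinophil or mast-like cells as the source. Among 6 reticular-like clusters KIT ran from 49.4 to 246 CPM, and it was among the leading genes of the highest, of 1778 cells. Other sources were not tested, and no biological explanation was tested.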

How the results depend on the processing

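The settings on low-UMI clusters, on unresolved endothelial clusters, without single clusters, and against the other tested genes were chosen after seeing the data, as were the list tests outside the planned ones (estimated correlation and no replicate block). Leaving out each library in turn gave 6596 to 6931 genes past the threshold for reticular-like against endothelial-like, 4974 to 5699 for osteolineage-like, 3336 to 4140 for fibroblast-like and 6539 to 7125 for mural against reticular-like cells. It gave 2239 to 2635 for arterial-like against sinusoidal-like and 6375 to 6991 for HSC or MPP-like against GMP-like cells. The other settings gave 6292 to 10339, 4586 to 6988, 3403 to 4964, 6698 to 9316, 1451 to 3791 and 5762 to 8191 genes, in the same order. Testing every gene with at least 1 count gave the 10339, with more genes tested. A minimum of 50 cells left 3 libraries for arterial-like against sinusoidal-like cells, with 1451 genes, 46.2% of them higher against 56.3% with a minimum of 20 cells. The other counts stayed within 1.5 times the main ones, though the genes called were not always the same. Of the 2557 genes called for arterial-like against sinusoidal-like cells, 1074 were also called with a minimum of 50 cells and 1694 with low-UMI clusters kept in their class. With the unresolved endothelial clusters counted as sinusoidal 1459 were (57.1%), 25 of them with the opposite direction. For HSC or MPP-like against GMP-like cells, 5388 of 6813 were also called without library correction, 94 of them with the opposite direction. The DESeq2 size factors moved the median log2 fold change of all genes most in mural against reticular-like cells, by -0.0642. The endothelial pair had the fewest genes with enough counts to be tested (4776). In the simulated data, recovery was lowest for fibroblast-like against reticular-like cells (84% of 2-fold and 98% of 4-fold changes).

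Without the replicate block, that is with the unpaired fit, 149 named genes kept their direction and their side of the threshold and 6 lost the call. In that fit 3 lists passed in HSC or MPP-like against GMP-like cells instead of 6, and 2 uncalled lists turned, the cell cycle in arterial-like cells (adjusted p = 0.969) and basement membrane in HSC or MPP-like cells (adjusted p = 0.998). Notch in reticular-like against endothelial-like cells (adjusted p = 0.0332) and bone remodelling and the cell cycle in osteolineage-like cells (adjusted p = 0.0498 each) were called, and it changed no other call. All 6 counts of genes with the unblocked fit stayed within 1.5 times the paired ones.

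Of the named genes, 155 of 155 kept direction and call with DESeq2 size factors, with the DESeq2 Wald test and with every gene with at least 1 count. Without library correction 143 did, 3 lost the call, and 2 turned without passing, CDCA3 (0.129) and ESCO2 (0.103), and the cause was not tested. Leaving out 1 library kept 1758 values and lost 6, all of CD36 in osteolineage-like cells.

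With an estimated correlation, 0 lists passed in each of the 6 comparisons. For reticular-like against endothelial-like cells (5 lists), 8 passed against the other tested genes, 11 with every gene with at least 1 count, 9 without library correction and 8 without the cluster led by PTGS2 and LIF. For HSC or MPP-like against GMP-like cells (6 lists), 3 passed with every gene with at least 1 count, 2 without library correction and 3 without the cluster led by replication genes. Against the other tested genes, 3 uncalled lists turned, VEGF signalling in fibroblast-like (adjusted p = 0.858), basement membrane in mural (adjusted p = 0.936) and the cell cycle in arterial-like cells (adjusted p = 0.974). Over the settings, 41 values of lists uncalled in the main test were called. For uncalled lists, 53 directions turned and 0 of those were called. List tests were not run with single libraries left out.

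Without replicate 1, r of the immediate-early level turned to -0.0465 for reticular-like and HSC or MPP-like cells and to -0.2499 for endothelial-like and HSC or MPP-like cells. The mean share of macrophage-like cells became 0.344% without library correction, 0.347% without doublet removal and 0.322% when clustered with the list genes. That of erythroblast-like cells became 0.241%, 0.330%, 1.12% and, with the stricter cell filter, 1.01%. Without doublet removal megakaryocyte-like cells had 2.23%, and without library correction unnamed cells 20.5%. For all these moves the cause was not tested. Of the 36 levels of the 6 niche genes, 5 moved by more than 1 SD without doublet removal, 1 with the stricter filter, 1 with the list genes and 0 without library correction.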

Other observations

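This part gives values chosen after they were seen, with no test. Several classes outside the comparisons carried niche genes. ANGPT1 stood at 217 ± 61.2 CPM in megakaryocyte-like cells (SD, n = 10), above the 128 CPM of mural cells and below the 768 CPM of reticular-like cells. CSF1, the growth factor of macrophages and osteoclasts, stood at 204 ± 98.9 CPM in erythroid progenitor-like cells (n = 11), against 174 CPM in reticular-like cells, and was among the leading genes of 1 erythroid progenitor-like cluster of 1133 cells. IL7 stood at 44.4 ± 16.9 CPM in erythroid progenitor-like cells, against 158 CPM in reticular-like cells.

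Fibroblast-like cells divided in 2 second-level clusters. A cluster of 1145 cells was led by MYOC, LAMA2, MFAP5, SFRP2 and IGF1, and a cluster of 676 cells by ASPN, COMP, RBP4 and OGN. Before that division, a cluster of 1863 fibroblast-like cells had PRG4, the gene of the joint lubricant lubricin, first among its leading genes. An unnamed cluster of 468 cells with few UMIs was also led by PRG4 and MMP3, with the macrophage gene C1QA.

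Endothelial-like cells of neither the arterial-like nor the sinusoidal-like class lay in a cluster of 2017 cells led by ABCB1, VWF and EMCN and a cluster of 1841 cells led by ACKR1, SELE and SELP. A lymphoid cluster of 2099 cells with GNLY, NKG7 and CD8A stayed unnamed because its leading genes belonged to the T cell-like and NK cell-like sets. An unnamed cluster of 2630 cells with HBB, HBA1 and KLF1 stood between the erythroid progenitor-like and erythroblast-like sets.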
